A study of Sus scrofa with 6 samples.

How the data were processed

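Liver tissue of newborn piglets was frozen, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, giving 3 libraries of the 2xTrp and 3 of the High-Low maternal diet. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the pig assembly susScr3. The step that made the expression values, the annotation and the strand setting are not given in the sources used here.

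The authors deposited 1 table per library with a value, coordinates and a length for each of 26733 genes. The headers give no unit. The deposited values were read as FPKM, because they are not whole numbers and because their totals differ between libraries (956426 to 1230288). An exact 0 may be a failed estimate in such values, and 59 genes had 20 FPKM or more in 1 library beside 0 in another. Since whole counts had been assumed when the design was fixed before the data were examined, the count models planned then were replaced by the test laid down for FPKM. Depth per library is unknown, and no counting interval can be given. Gene symbols came from a table of Ensembl identifiers, which named 11804 of 25322, and the 1411 features with the authors' own identifiers (such as Novel01392) have no symbol.

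Genes with 1 FPKM or more in at least 3 libraries (10901 genes, 6532 with a symbol) were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a moderated variance with a mean trend and robust estimation. Fold changes are on that scale, which understates the change of genes with low values. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. FPKM were used as deposited, without further scaling. Intervals are 95% intervals from limma. Fold changes are High-Low minus 2xTrp.

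Before the data were examined, 40 gene lists were fixed, covering pathways of liver metabolism, stress, immunity and markers of cell types. The 37 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. AHR target genes, fetal liver genes, and megakaryocyte and platelet markers had 4, 4 and 1 tested members and were not tested as lists. Members were matched by symbol as spelled, and 134 of 962 list symbols have no identifier in the symbol table. The named genes follow a rule fixed at the same time: called genes with a symbol, filled up to 8 per direction by the smallest p, the 4 members of smallest p of each list described, and a fixed set of liver genes. Genes named outside it are said to have been chosen after their values were seen. IGF2 of that set had no identifier in the symbol table. The distance between libraries was compared over all 10 splits of the 6 libraries by an exact permutation test.

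The limma step was tested on simulated data: 20 runs of 10901 genes with 200 changed genes each. Means were the real ones, and the spread was limma's moderated variance, which is less extreme than the observed variance. The limma step recovered 28.3% of genes changed by 1 on the log2 scale, 92.1% at 2, 97% at 3 and 98.4% at 4. The median was 9 false calls per run. The changed genes were drawn from those with a mean log2 value over 3, and the noise was independent between genes. Many true changes make the adjusted threshold easier to reach. These shares therefore do not hold for genes with lower values or for data with few changes. The list test found the shifted list in 20 of 20 runs with independent genes, and called at most 1 list where none was shifted. Genes of the lists called in the real data were correlated (estimates 0.109 to 0.782). These runs therefore do not give the rate of false list calls here, and other splits of the real libraries called 2 to 12 lists. Alternatives tried were other scalings, other filters on low values, another pseudocount, variance estimation without robustness or trend, sample weights, a block for the replicate number and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.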

Results

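Liver RNA of newborn piglets (Landrace × Yorkshire crosses) was sequenced after their mothers had been fed tryptophan on 1 of 2 daily schedules. Sows of the 2xTrp group received feed with 0.26% tryptophan at both the morning and the afternoon meal. Sows of the High-Low group received 0.39% in the morning and 0.13% in the afternoon. Each group had 3 libraries, and the series title frames the comparison as a search for liver genes linked to negative effects of dietary tryptophan. Values were read as FPKM for 26733 genes, and their totals ran from 956426 to 1230288 per library. Read depth is unknown, because these values keep no read counts. The labels do not say that the libraries came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

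The High-Low and 2xTrp livers differed in 1 transcript past the threshold. Novel01392, a feature without a gene name at positions 1 to 1122 of the mitochondrial sequence in the susScr3 assembly, ahead of the first annotated gene at 1176, rose from 4.54 ± 1.44 FPKM in 2xTrp to 282 ± 72.0 in High-Low (SD, n = 3 each). Its log2 fold change was 5.68 (SE 0.29), with an adjusted p of 0.0015 in limma, and it was higher in all 3 High-Low libraries than in any 2xTrp library. That stretch precedes the mitochondrial genes and is the control region in mammalian mitochondrial DNA, where replication and transcription start. An unnamed feature on chromosome 10, Novel00135 at 73620195 to 73628656, has a listed length of only 101. It had 832 ± 234 FPKM in 2xTrp and 156 ± 20.7 in High-Low (SD, n = 3 each). Its log2 fold change of -2.38 missed the threshold in limma, with an adjusted p of 0.0848. Scaling each library to its FPKM total brought Novel00135 to an adjusted p of 0.0114 (range over 19 alternatives 0.0114 to 0.412), which makes 1 gene higher and 1 lower in place of 1 and 0. Both features were chosen after their values were seen.

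Of 10901 genes tested, 1 was higher and 0 were lower in High-Low at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 345 genes, 136 higher and 209 lower, or 3.16% of those tested. The 3 High-Low values lay entirely on one side of the 3 2xTrp values for 783 genes (7.18%), where chance gives 10%. Without High-Low replicate 2, an unadjusted p under 0.05 was reached by 623 higher and 789 lower genes, while 1 and 0 passed the threshold. Without 2xTrp replicate 3, 2 genes were higher, the second being ENSSSCG00000026167, which is listed at 0 in 2xTrp 1 and 2xTrp 2 and at 11986 FPKM in 2xTrp 3.

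Messenger RNAs encoded by the mitochondrial genome, which make subunits of the respiratory chain and of ATP synthase, rose as a list in High-Low. All 13 had a positive log2 fold change, with a median of 0.89, and the list passed the set test (camera, adjusted p = 2.1e-17). The call was lost with an estimated correlation (adjusted p = 0.932 with an estimated correlation). That estimate was 0.726 for this list, far above the preset 0.01, so the smaller p overstates the evidence. Adjusted over the list alone, 9 of the 13 were higher, and adjusted over all genes tested, 0 were. ND1, a complex I subunit, had 1137 ± 317 FPKM in 2xTrp and 2853 ± 455 in High-Low, and ND6 had 327 ± 155 and 1224 ± 293 (SD, n = 3 each). ND2 had 342 ± 123 FPKM against 1234 ± 506, ND4L 371 ± 115 against 1430 ± 719, and the complex IV subunit COX3 9888 ± 2320 against 17947 ± 2375. ATP6 and ND4, named after their values were seen, stood lowest in the list, at log2 fold changes of 0.27 and 0.38. The features without a symbol at 1246 to 2205 and 2274 to 3844 of the mitochondrial sequence had 8.52 ± 3.12 FPKM in 2xTrp against 8.60 ± 2.96 in High-Low and 53.9 ± 39.3 against 53.9 ± 17.3. ATP8 overlaps ATP6 and ND4L overlaps ND4 on the same strand, and how shared reads were assigned is not given in the sources used here. ND6 overlaps ND5 on the opposite strand, and whether counting used the strand is not given either, so the values of these pairs are uncertain. The mitochondrial sequence held 3.48%, 5.20% and 4.16% of the FPKM total in the 2xTrp libraries and 10.02%, 5.83% and 6.79% in the High-Low libraries. Nuclear genes of the respiratory chain had a median log2 fold change of 0.011 over 29 members, 16 positive and 13 negative (adjusted p = 0.811). That list passed as higher without High-Low replicate 3 (median 0.14, adjusted p = 0.0079) and as lower with array quality weights (-0.26, adjusted p = 0.0191).

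**Figure D1:**
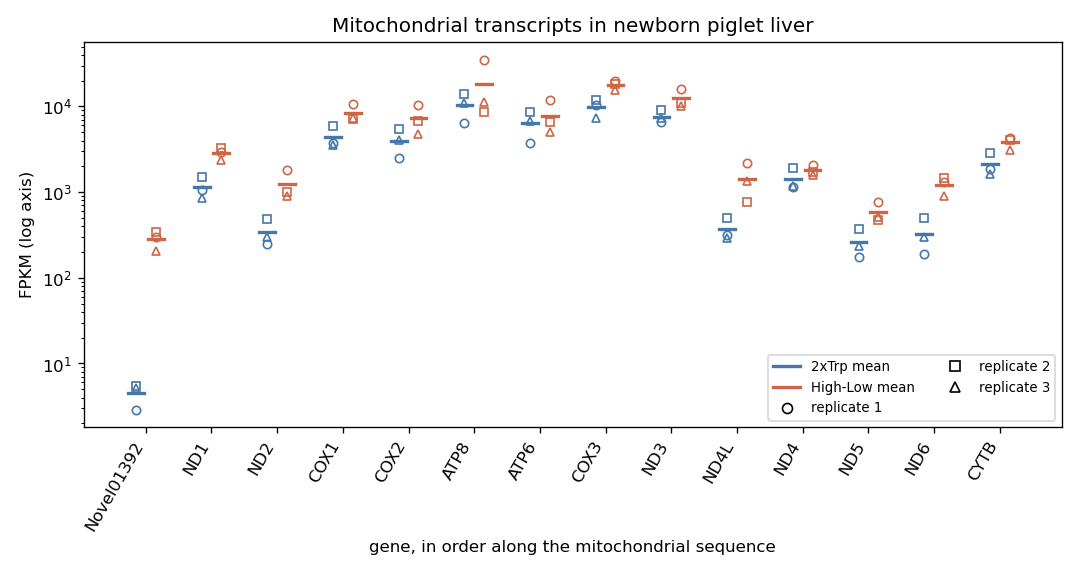
FPKM (log axis) of Novel01392 and of the 13 mitochondrially encoded messenger RNAs, in order along the mitochondrial sequence, with 1 symbol per library and a horizontal bar for each group's mean. Novel01392 averaged 4.54 FPKM in 2xTrp and 282 in High-Low, and ND1 averaged 1137 and 2853.

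Markers of endothelial cells and of macrophages fell in High-Low as lists. All 14 tested endothelial markers were negative, with a median log2 fold change of -0.42 (camera, adjusted p = 1.6e-05). That call was lost with an estimated correlation, which was 0.357 (adjusted p = 0.932 with an estimated correlation). PECAM1, an adhesion molecule of the vessel wall, had 38.7 ± 6.69 FPKM in 2xTrp and 25.7 ± 6.95 in High-Low, and ROBO4 had 4.17 ± 1.40 and 2.02 ± 0.451 (SD, n = 3 each). STAB1 had 18.5 ± 4.67 FPKM against 12.4 ± 3.27, and CLEC14A 22.9 ± 5.45 against 16.2 ± 1.35. Of 9 macrophage markers 8 were negative, with a median of -0.53 (camera, adjusted p = 9.4e-04). This call too was lost with an estimated correlation, which was 0.371 (adjusted p = 0.932 with an estimated correlation). Without High-Low replicate 2 the macrophage median was -0.56 with an adjusted p of 0.0717. CSF1R, the receptor that maintains macrophages, had 18.0 ± 1.38 FPKM against 9.82 ± 2.74, C1QA 418 ± 72.3 against 267 ± 88.3, and TIMD4, which marks resident liver macrophages, 39.9 ± 5.88 against 26.5 ± 5.70. CD68 had 29.6 ± 8.88 FPKM against 17.8 ± 4.31. The 1 positive member, MARCO, named after its values were seen, had 9.92 ± 3.29 and 14.5 ± 5.11 FPKM. High-Low 1 stood apart in these markers. Its mean endothelial log2 value, relative to the mean of all libraries, was -0.47, against -0.05 and -0.07 in High-Low 2 and High-Low 3 and 0.30, -0.09 and 0.38 in the 2xTrp libraries. For macrophage markers the values were -0.48, -0.16 and 0.01 in High-Low and -0.11, 0.31 and 0.44 in 2xTrp. The groups overlapped in both lists. Several other lists were lowest in High-Low 1 as well. They stood at -0.80 for antigen presentation, -0.50 for lymphocytes, -0.46 for bile duct cells, -0.32 for stellate cells and -1.16 for erythroid cells. Neutrophil markers were lowest in 2xTrp 2, at -0.40, with High-Low 1 at -0.39. The macrophage call was also lost with array quality weights (-0.34, adjusted p = 0.0712). Adjusted over the list alone, 0 endothelial and 0 macrophage markers passed.

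Blood cell genes moved in opposite directions as lists. All 7 erythroid genes were negative, with a median log2 fold change of -0.27 (camera, adjusted p = 0.0135; adjusted p = 0.932 with an estimated correlation). HBB, the beta chain of haemoglobin, had 12342 ± 5418 FPKM in 2xTrp and 4406 ± 2666 in High-Low, and ALAS2, the first enzyme of haem synthesis in red cells, had 46.0 ± 20.2 and 17.7 ± 8.43 (SD, n = 3 each). HBM had 83.8 ± 39.3 against 46.6 ± 31.2 FPKM, and TRIM10 1.75 ± 0.787 against 1.28 ± 0.360. HBB was lowest in High-Low 1, at 1793 FPKM. All 8 neutrophil and granulocyte precursor genes were positive, with a median of 0.56 (camera, adjusted p = 0.00691; adjusted p = 0.932 with an estimated correlation), and High-Low 2 led them. The granule protease ELANE had 15.2 FPKM in High-Low 2 and at most 5.52 in any other library. S100A8 had 18.6 ± 3.14 FPKM in 2xTrp and 33.7 ± 22.0 in High-Low, LTF, which encodes lactoferrin, 2.54 ± 0.281 and 4.66 ± 2.10, and LCN2 2.42 ± 0.674 and 5.23 ± 3.46. Without High-Low replicate 2 the neutrophil median was -0.01 (adjusted p = 0.930), and without 2xTrp replicate 2 it was 0.48 (adjusted p = 0.0675). It was 0.92 without High-Low replicate 1, and the call was lost without a filter on low values (0.38, adjusted p = 0.0791) and with array quality weights (0.19, adjusted p = 0.443). The erythroid median was -0.26 without 2xTrp replicate 3, -0.18 without High-Low replicate 1 and -0.37 without High-Low replicate 2, and the call was lost each time (adjusted p = 0.241, 0.419 and 0.136). The median was -0.69, -0.50 and -0.47 without High-Low replicate 3, 2xTrp replicate 1 and 2xTrp replicate 2, with the call kept, and -0.47 with a pseudocount of 0.1 (adjusted p = 0.0123). With array quality weights it was -0.37 (adjusted p = 0.358). Adjusted over the list alone, 0 genes of either list passed.

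Enzymes of amino acid catabolism fell as a list in High-Low, with 23 of 29 members negative and a median log2 fold change of -0.20 (camera, adjusted p = 0.0277; adjusted p = 0.932 with an estimated correlation). OAT, which degrades ornithine, had 20.1 ± 12.4 FPKM in 2xTrp and 6.73 ± 0.640 in High-Low (SD, n = 3 each). The lowest OAT value was in 2xTrp 3, at 5.74 FPKM, against 27.4 and 27.2 in 2xTrp 1 and 2xTrp 2. HAL and UROC1, which carry out successive steps of histidine breakdown, had 78.7 ± 22.0 against 46.2 ± 25.4 and 162 ± 26.9 against 111 ± 60.2 FPKM. High-Low 2 had the lowest HAL, at 23.2 FPKM against 42.0 and 73.5 in High-Low 1 and High-Low 3. For UROC1 it was the highest High-Low library, at 180 FPKM against 80.4 and 72.2. GLDC of the glycine cleavage system went the other way, at 12.8 ± 3.43 and 21.6 ± 8.86 FPKM. High-Low 3 had the lowest mean log2 value of the list, at -0.37 relative to the mean of all libraries. It was also lowest for hepatocyte markers (-0.26) and the nuclear-encoded respiratory chain (-0.27). Without High-Low replicate 3 the median was -0.02 (adjusted p = 0.604), and without 2xTrp replicate 2 it was -0.18 (adjusted p = 0.127). The call was lost with quantile normalization (-0.13, adjusted p = 0.137) and with a filter at 5 FPKM (-0.20, adjusted p = 0.145). The median was -0.33 without High-Low replicate 2 and -0.47 with array quality weights, both past the threshold. Adjusted over the list alone, 0 members passed.

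The tryptophan and kynurenine pathway, the route most directly tied to the diets, did not pass the set test (adjusted p = 0.683). Of its 12 tested members 5 were positive and 7 negative, with a median log2 fold change of -0.05. TDO2, which opens the liver's tryptophan degradation, had 91.2 ± 59.5 FPKM in 2xTrp and 76.2 ± 46.3 in High-Low (SD, n = 3 each). Its log2 fold change was -0.21, with a 95% interval from -1.73 to 1.31, so changes of more than 2-fold in either direction were not excluded. The direction turned without 2xTrp replicate 3 (0.28) and without High-Low replicate 2 (0.31). KMO, the hydroxylase of the kynurenine route, had 36.6 ± 7.26 and 41.5 ± 25.4 FPKM, and its log2 fold change ran from -0.45 without High-Low replicate 1 to 0.50 without High-Low replicate 2. DDC, which decarboxylates aromatic amino acids, had 37.1 ± 12.1 and 55.5 ± 15.4, and KYAT1 had 46.3 ± 12.3 and 32.1 ± 8.01. MAOB had 145 ± 6.71 against 119 ± 18.4 FPKM, and QPRT 81.1 ± 14.2 against 64.8 ± 19.6. The receptor AHR, which binds kynurenine, lay under 1 FPKM in both groups (0.566 ± 0.365 and 0.778 ± 0.215) and was not tested. Its targets CYP1A1 and CYP1A2 had 1.93 ± 2.45 against 3.99 ± 2.54 and 3.22 ± 2.03 against 8.20 ± 7.80 FPKM, without passing the test. High-Low 1 carried most of the CYP1A2 difference, with 17.1 FPKM against 4.99 and 2.53 in the other High-Low libraries. The log2 fold change of CYP1A2 was 0.89, and 0.23 without High-Low replicate 1. CYP1A1 had 4.76 FPKM in 2xTrp 2 against 0.33 and 0.71 in 2xTrp 1 and 2xTrp 3. Its log2 fold change was 0.91, and 1.56 without 2xTrp replicate 2.

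Among single nuclear genes with a symbol, 0 passed the threshold in limma, and the following are values that did not pass (adjusted p = 0.998 each). The genes of smallest p on the higher side were SMPD3, a sphingomyelinase, at 2.45 ± 0.679 FPKM in 2xTrp and 7.51 ± 1.14 in High-Low, RGS16, a regulator of G protein signalling, at 31.7 ± 1.95 and 70.1 ± 21.8, and the histone gene H2BC5 at 14.6 ± 0.760 and 28.3 ± 6.71 (SD, n = 3 each). On the lower side TMEM158 had 5.44 ± 0.434 and 1.47 ± 0.718 FPKM, PHYHD1 192 ± 20.2 and 95.6 ± 13.9, and SNX20 1.89 ± 0.188 and 0.471 ± 0.213. The beta-1 adrenergic receptor ADRB1 had 3.14 ± 0.751 and 1.13 ± 0.250 FPKM, and EPHX2, an epoxide hydrolase, 119 ± 10.3 and 72.1 ± 7.28. SLC3A2, the heavy chain of large neutral amino acid transporters that carry tryptophan, had 42.9 ± 9.20 and 22.1 ± 4.17 FPKM. HEXIM1 had 50.3 ± 11.2 and 28.0 ± 1.63, and RFTN1 5.93 ± 1.05 and 2.23 ± 1.11. The liver products ALB and AFP had 12020 ± 2996 against 17650 ± 3549 and 1554 ± 604 against 1858 ± 131 FPKM. PCK1, an enzyme of glucose synthesis, had 400.0 ± 127 and 401 ± 75.0, and the growth factor IGF1 had 0.764 ± 0.525 and 2.05 ± 1.36.

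Of 37 gene lists with enough tested members, 6 passed with a preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.932), by fry (0.970) or by fry without direction (0.531). The 6 that passed had estimated correlations of 0.109 to 0.782, against the preset 0.01, so their p-values at the preset overstate the evidence. The other 31, among them the urea cycle, cholesterol synthesis, the circadian clock and cytosolic ribosomal proteins, had adjusted p from 0.111 to 0.988 and medians from -0.46 to 0.29. Without High-Low replicate 2, and with a filter at 5 FPKM, 3 lists passed. Of the 31, 7 passed when 1 library was left out. Cholesterol synthesis passed as higher without 2xTrp replicate 2 (0.27, adjusted p = 0.0174) and as lower without 2xTrp replicate 3 (-0.31, adjusted p = 0.0355). The others were fatty acid and triglyceride synthesis, extracellular matrix, stellate cell, lymphocyte, interferon-stimulated and nuclear respiratory chain genes. In 11 of those 31 the median, the mean and the test differed in sign.

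**Figure D2:**
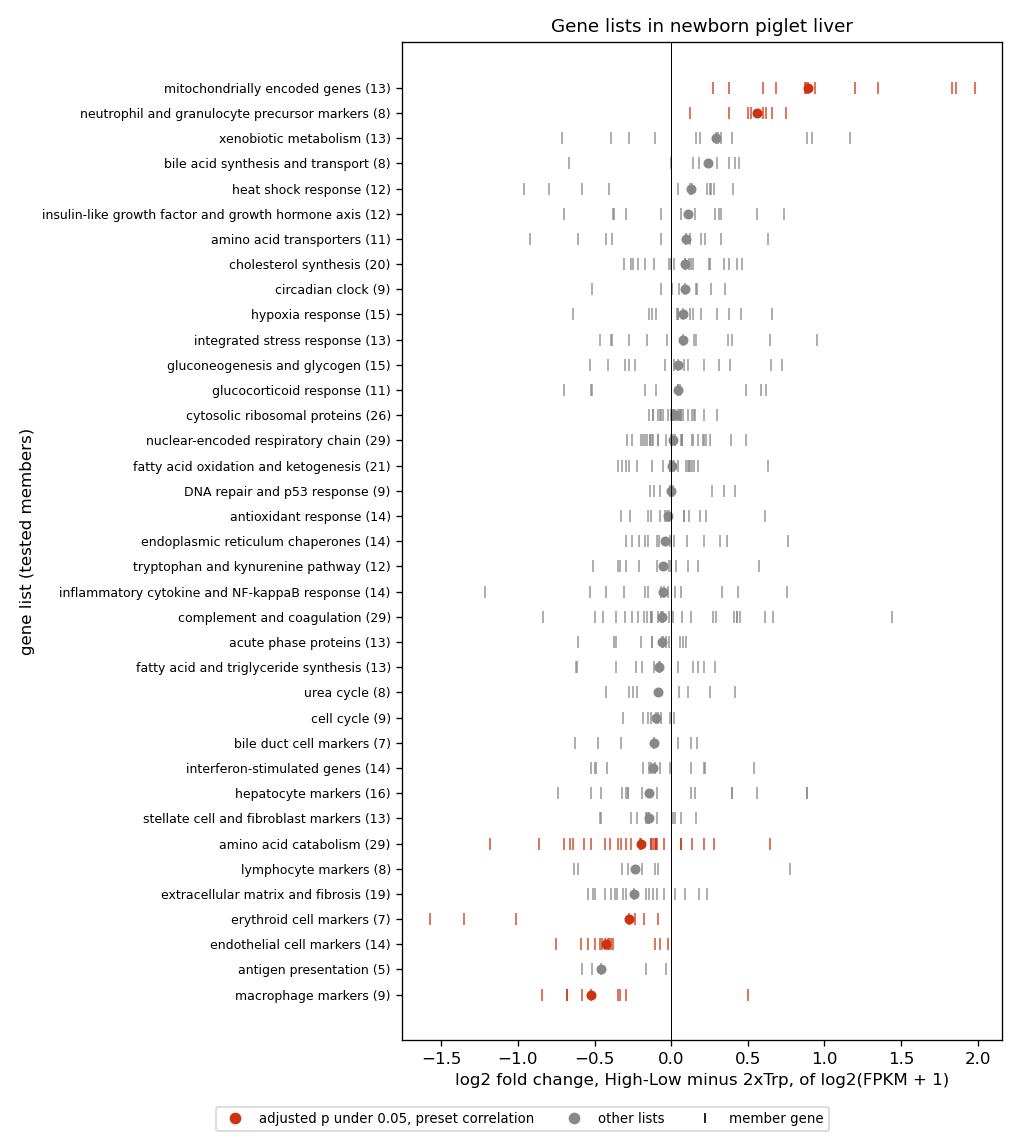
Log2 fold changes (High-Low minus 2xTrp, on log2 of FPKM plus 1) of the tested members of 37 gene lists, with a tick per gene and a point at each list's median; red marks lists under an adjusted p of 0.05 with the preset correlation. The mitochondrially encoded genes lie highest, at a median of 0.89, and the macrophage markers lowest, at -0.53.

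The whole profiles of the libraries did not separate by group. The mean rank distance (1 minus Spearman's rho over the tested genes) was 0.0734 between groups, 0.0665 within 2xTrp and 0.0902 within High-Low. The difference between and within groups was -0.0049, and 6 of the 10 splits of the 6 libraries gave as large a value (exact permutation p = 0.6, one-sided, where 0.1 is the smallest this design allows). Without High-Low replicate 2 the difference turned to 0.0108 (exact permutation p = 0.1). The first principal component held 36.1% of the variance and set High-Low 1 and High-Low 2 at opposite ends, at 46.5 and -38.6.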

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

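Array weights, quantile normalization, scaling to nuclear genes, a filter at 5 FPKM and the fit without a variance trend were chosen after seeing the data; the rest were planned. DESeq2 and limma-voom, with and without sample weights, were not run because the values were read as FPKM. A filter of 1 FPKM in 3 libraries is the filter already used. Novel01392 stayed past the threshold in all 19 alternatives (log2 fold change 5.29 to 5.95, adjusted p 8.1e-05 to 0.021), and without single replicates 1 to 2 genes were higher. The count of lower genes went from 0 to 1 with scaling to the FPKM total, to the total without the 20 most abundant genes or to nuclear genes, with quantile normalization, with array weights, and at an adjusted p under 0.1. Array weights took 768 genes higher and 1021 lower to an unadjusted p under 0.05. The gene lists called went from 6 to 0 with an estimated correlation, to 0 by fry and to 3 with the filter at 5 FPKM, under which the erythroid and neutrophil lists had too few members to test; leaving out single replicates gave 3 to 9. Array weights gave 4 lists, without the macrophage, neutrophil and erythroid lists and with the nuclear respiratory chain; no filter gave 5, without the neutrophil list, and quantile normalization 5, without amino acid catabolism. The mitochondrial and endothelial lists passed in 20 of 22 alternatives each, failing with an estimated correlation and with fry. All 20 kept the preset correlation of 0.01, while the estimates were 0.726 and 0.357. These passes therefore do not test that setting. Separation ran from -0.0128 to 0.0108 without single replicates. With the replicate number as a block (replicate block), 1 gene was higher, 0 were lower and 6 lists passed. Libraries of the same number had correlated deviations of -0.216, -0.0113 and 0.0323, and none correlated best with its own number. No scaling moved the median of all genes by over 0.1.

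Directions turned for KMO, PCK1, TDO2, ELANE and the tryptophan and nuclear respiratory chain lists. KMO was at -0.00395 with a pseudocount of 0.1. Without single replicates KMO ran from -0.45 to 0.50, PCK1 from -0.25 to 0.23, TDO2 from -0.80 to 0.31 and ELANE from -0.011, without High-Low replicate 2, to 1.00. The median of the tryptophan list ran from -0.17 to 0.0010, and its test direction turned without High-Low replicate 3 (-0.044). The nuclear respiratory chain stood at -0.26 with array weights and ran from -0.093 to 0.14 without single replicates. Of 938 values for 50 named genes under alternatives, 922 kept direction and side of the threshold and 5, all of Novel00135, passed it. Apart from Novel01392 and Novel00135, these genes lay far from the threshold (adjusted p of 0.998 or more in limma). Many were also picked by their p in these same data, so that share says little about robustness. Where values changed, the cause was not tested. Unknown depth limits all of these values, and genes near 1 FPKM most.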

Other observations

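The tests and the genes below were chosen after the values were seen. Single libraries stood apart in some transcripts. FOS, an immediate early gene induced within minutes of stimulation, had 174 FPKM in High-Low 2 and 2.35 to 23.3 in the others. DUSP1 had 318 FPKM there and 34.9 to 129.5 elsewhere, and ATF3 had 12.2 against 1.04 to 2.81. EGR1 and IER2, which are immediate early genes too, were highest in 2xTrp 1, at 101 and 47.5 FPKM, and had 23.1 and 43.2 in High-Low 2. High-Low 1 had the highest P4HA1, a hypoxia-induced collagen hydroxylase, at 48.9 FPKM, against 3.61 in High-Low 2, and IGFBP1 had 2925 FPKM in High-Low 1 and 187 in High-Low 2. APOB, the main protein of very low density lipoprotein, had 22.6 FPKM in High-Low 1 and 1.37 to 3.82 in the other libraries.

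Groups of 3 and 3 libraries make too few splits for a share under 0.05. The real split called 1 gene and 6 lists, and the highest of the other splits called 2 genes and 12 lists. As many genes were called in 6 of the 10 splits and as many lists in 8. The median of the mitochondrially encoded genes was 0.89 in the real split and at most 0.80 in the others, so 1 split, the real one, reached it.

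Novel01392 rose far more than the mitochondrial messenger RNAs. A uniform rise of mitochondrial RNA is argued against, because the log2 ratio of Novel01392 to the geometric mean of the 13 named genes differed between groups by 4.92 (SE 0.32). The features at 1246 to 2205 and 2274 to 3844 had ratios of High-Low to 2xTrp means of 1.01 and 1.00. Their 2xTrp means were 8.52 and 53.9 FPKM, while the lowest among the named messenger RNAs was 260 (ND5). Which RNAs these features hold, and how far library preparation kept them, was not checked. Their ratios therefore do not decide whether mitochondrial RNA rose uniformly. Mitochondrial DNA haplotypes of the mothers that align differently to the reference stay open beside the diet: the log2 gap of 5.21 between the groups restates the pattern and favours neither. Without reads or litter labels the 2 cannot be told apart.

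For the mitochondrially encoded messenger RNAs, the median was 0.96 (SE of the list mean 0.29) after scaling to nuclear genes. That could not decide whether scaling is the cause, because the mitochondrial sequence held only 3.48% to 10.02% of the FPKM totals. A scaling difference would shift all genes alike, and the median of all tested genes was -0.0038. The list median was 0.92 with median-of-ratios and 0.93 with upper-quartile scaling, so a scaling factor shared by all genes is argued against. A rise of nuclear respiratory genes as large as that of the mitochondrial ones is argued against too, since nuclear-encoded members had a median of 0.011. A smaller rise stays open. The SD of 0.19 is over the 29 genes and not over libraries. Their mean log2 values, relative to the mean of all libraries, were -0.13, 0.03 and 0.07 in 2xTrp and 0.13, 0.17 and -0.27 in High-Low. Where that list passed, its median was 0.14 without High-Low replicate 3 and -0.26 with array weights. A difference in RNA quality was not measured and may remain, as may the diet. The share of cell types, taken up below for the endothelial markers, was not tested for these genes and may remain as well. Relative to all libraries, High-Low 1 had the highest mean log2 value for the mitochondrial list (0.97) and the lowest for endothelial markers (-0.47). 2xTrp 2 stood apart from the other 2xTrp libraries in both, at -0.05 against -0.87 and -0.66, and at -0.09 against 0.30 and 0.38. Mitochondrial haplotypes that align differently, left open above for Novel01392, were not checked for these genes and may remain too.

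The lower endothelial and macrophage markers may reflect fewer cells other than hepatocytes, or the state of High-Low 1. Without High-Low 1 the endothelial median was -0.30 and the macrophage median -0.45 (camera, adjusted p = 0.00317 and 0.0149). With an estimated correlation neither passed without that library (adjusted p = 0.994 each with an estimated correlation). Neither had passed with all 6 libraries (adjusted p = 0.932 each with an estimated correlation), so that test cannot show the part of High-Low 1. The medians moved toward 0 from -0.42 and -0.53 but stayed negative, and the part of High-Low 1 stays open. Other lists that did not pass had negative medians too, of -0.46 for antigen presentation, -0.24 for lymphocytes, -0.15 for stellate cells and -0.11 for bile duct cells, and hepatocyte markers had -0.14 with a mean of 0.014. Neutrophil markers, which fewer such cells would lower alike, had a positive median: the endothelial to neutrophil difference was -0.91 (SE 0.45) and -0.48 without High-Low 2, so it rests partly on 1 library and this explanation stays open too, as does the diet.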
